A study of Bos taurus with 21 samples.

How the data were processed

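Endometrium, the lining of the uterus, was profiled by RNA sequencing in 20 cross-bred beef heifers. Per the labels' protocols, the oestrous cycles were synchronised with a progesterone-releasing vaginal device and a prostaglandin analogue, 54 heifers were seen in oestrus, 38 of them were inseminated and 16 were kept as cyclic controls. Heifers were slaughtered on day 13 or day 16. Mostly intercaruncular endometrium, the tissue between the sites where the placenta attaches, was taken after flushing from the horn on the side of the corpus luteum, and inseminated heifers entered the study only if a conceptus at the proper stage was recovered. Single-read Illumina libraries were made, per the labels' protocols.

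The deposited values were raw read counts per transcript for 28054 Ensembl bovine transcript identifiers in each of 21 libraries. CASAVA is named in the submitters' processing notes with no version or role. The aligner, the counting program, the annotation release and the genome build are not given in the sources used here. Whether the counting used strand, and how it shared reads between transcripts of one gene or between paralogous genes, is also not given, so counts of overlapping transcripts are uncertain. Of 15643 identifiers with at least 100 counts over all libraries, 56 had the same counts as another identifier in every library, and none of these was among the transcripts called for pregnancy at day 16. The files do not pair the identifiers with gene names, and 0 of them matched the reference table of gene names used here. For that reason results are given for transcripts and for groups of transcripts, 4 identifiers are named, and the 27 gene lists fixed before the data were examined (interferon-stimulated genes, prostaglandin and steroid pathways, cell type markers and others) were not tested.

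Groups were taken from the sample labels: cyclic day 13, pregnant day 13, cyclic day 16 and pregnant day 16, with 5 heifers in each. The labels number the heifers from 1 to 20 with no number shared between groups, so the comparisons were unpaired. Heifer 12 of the pregnant day 16 group had 2 libraries, which were summed to 1 replicate as fixed before the data were examined. Total counts ranged from 1256870 to 3764342 per library, and heifer 12 had 5621055 after summing. A floor of 3 counts corresponded to 0.532 CPM in the deepest heifer and 2.38 CPM in the shallowest. Reads without molecular identifiers are not independent molecules, so floors and counting intervals cover counting error only.

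Transcripts were kept by the filterByExpr function of edgeR (version 4.0.16, in R 4.3.3) with a minimum count of 10 and a minimum total of 15, which left 14807 of them, and 6507 identifiers had no count in any library. Counts were scaled with trimmed mean of M values (TMM) factors. A quasi-likelihood negative binomial model with robust estimation was fitted to all 20 heifers with 4 group means. Contrasts gave pregnant against cyclic at each day, the difference between these pregnancy effects, and day 16 against day 13 in cyclic and in pregnant heifers. P-values were adjusted by the Benjamini-Hochberg method, and a transcript was called at an adjusted p under 0.05. Standard errors were derived from the fold change and the F statistic. Values per heifer are CPM, read counts scaled to a common library total with TMM factors, and log2 CPM used a prior count of 2. Means are given with the standard deviation (SD).

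The rule for naming genes required a gene symbol, which no identifier had. Without that condition its first part takes called transcripts with a mean of at least 1 CPM in the higher group and no overlap between the 5 and 5 heifers, ranked by fold. The first 2 that were higher and the only one that was lower were named in this way. A second lower transcript, ENSBTAT00000026346, was chosen after its values were seen.

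The set of transcripts called as higher in pregnant heifers at day 16 was averaged per heifer as mean log2 CPM. Pregnant and cyclic heifers at day 13, whose difference was not part of the contrast that chose the set but which shared its filter, scaling and dispersion estimates, were compared by an exact two-sided permutation test over 252 arrangements. At day 16 each heifer was also left out in turn, the set was chosen again from the other 19 heifers, and the level of the set in the heifer left out was compared with the mean of the other cyclic day 16 heifers. Correlations of edgeR fold changes were computed across transcripts, which are not independent replicates. Pearson correlations of differences of mean log2 CPM were set against 1000 reassignments of heifers within each pair of groups.

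Libraries were compared by a chi-square statistic over transcripts with at least 20 counts in the pair. They were also compared by the correlation of log2(CPM + 0.5) over 33 transcripts that were close to on or off. These had under 0.8 CPM in at least 3 libraries, over 5 CPM in at least 3 and a maximum over 15 CPM, judged in the 18 libraries other than those labelled heifers 12 and 19. The comparison with heifer 19 was chosen after the first result had been seen. Letters A to D in the names under which the libraries were deposited were read as sequencing runs, which is an inference. Runs A, B and C held animals of 3 or 4 groups, and run D, with 1 library, was joined to run C.

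Counts were simulated for the same 14807 transcripts, each with the same dispersion in all groups. The fit was tested on them with 200 transcripts changed, drawn at random, 100 by 2-fold and 100 by 4-fold. For pregnant against cyclic it found 69% of the 2-fold and 97% of the 4-fold changes at day 16, with 12 false calls among 178, and 76% and 97% at day 13, with 13 false among 186. For day 16 against day 13 it found 74% and 97% in cyclic heifers, with 8 false among 179, and 59% and 95% in pregnant heifers, with 1 false among 155. For the difference between the pregnancy effects it found 37% and 85%, with 3 false among 125.

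Alternatives fixed before the data were examined were other size factors, no filter on low counts, DESeq2 (version 1.42.0), limma voom with quality weights (version 3.58.1), only the groups compared, either library of heifer 12 alone, the run letter as a term, and each heifer left out in turn. Thinning every heifer to the smallest total, moving library 2 labelled heifer 12 to heifer 19, and leaving out day 13 heifers with the set kept were added after the data were seen. No deposited library was left out.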

Results

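Transcript abundance was measured in the endometrium of 5 cyclic and 5 pregnant heifers on day 13 after oestrus, when the bovine conceptus starts to elongate, and of 5 cyclic and 5 pregnant heifers on day 16, when the mother recognises the pregnancy. In cattle the elongating conceptus secretes interferon tau, the signal that prevents the regression of the corpus luteum. The comparisons asked which endometrial transcripts differed between heifers with and without a conceptus at each day, and which changed over the same days in each. Mean total counts were 2560081 ± 255748 (SD, n = 5) in cyclic day 13, 2579162 ± 751574 (n = 5) in pregnant day 13, 2594366 ± 334842 (n = 5) in cyclic day 16 and 2976902 ± 1655528 (n = 5) in pregnant day 16 heifers. The 10 most abundant transcripts took between 2.87% and 3.73% of the counts in each library.

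The 2 libraries labelled pregnant day 16 heifer 12 differed from each other by more than many pairs of different heifers. Their chi-square per degree of freedom was 6.85, rank 51 of 210 library pairs from the closest, and their correlation over 33 transcripts that were close to on or off was 0.234. The library labelled heifer 12, library 2, was closest to the library labelled heifer 19, with a chi-square per degree of freedom of 2.0 against at least 3.30 in the remaining pairs. Their correlation over the on-off transcripts was 0.965, against at most 0.690 in the remaining pairs. Every value below for heifer 12 is the sum of the 2 libraries so labelled. With library 1 alone, 142 transcripts were called for pregnancy at day 16, and with library 2 summed with heifer 19, 144 were called. The change between days in pregnant heifers depended more on this choice. It gave 587 calls with library 1 alone and 798 with library 2 alone, against 688 with the sum. Calls shared in direction with cyclic heifers numbered 120 with library 1 alone and 160 with library 2 alone, against 140 with the sum.

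**Figure D1:**
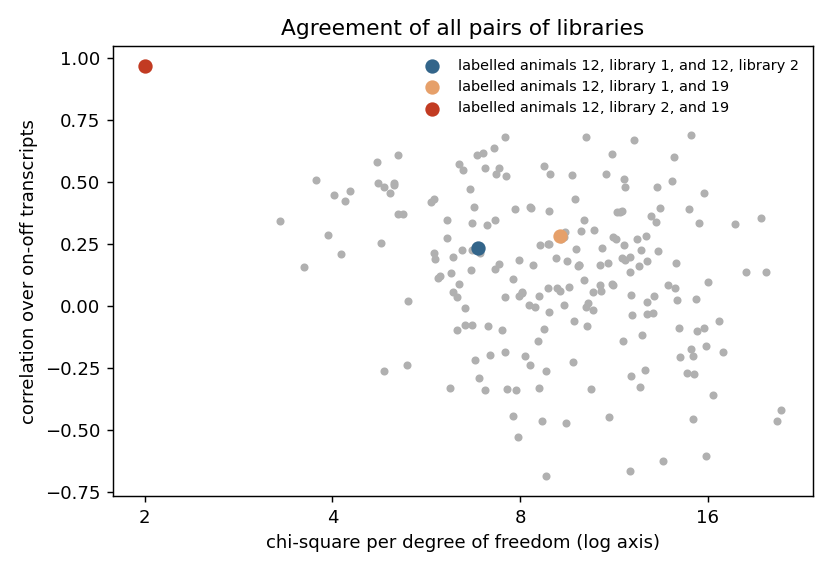
Each point is 1 of 210 pairs of libraries, placed by the chi-square per degree of freedom between their counts (horizontal log axis, lower is closer) and by the correlation of their log2 values over 33 on-off transcripts (vertical axis). The pair of library 2 labelled heifer 12 with heifer 19 (red) stands apart at 2.0 and 0.965, and the 2 libraries labelled heifer 12 (blue) lie among pairs of different heifers.

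At day 16 the transcripts that differed between pregnant and cyclic heifers were almost all higher in the pregnant ones. Of 14807 transcripts tested, 141 were higher and 3 were lower in the 5 pregnant than in the 5 cyclic heifers (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The higher transcripts had a median log2 fold change of 1.77, with a range of 0.57 to 7.07, the highest being a fitted value for a transcript with 1 count in cyclic heifers. Of these 141, 61 were at least 4-fold higher and 29 were less than 2-fold higher. The median log2 fold change over all transcripts tested was -0.002. In 136 of the 141 the lowest pregnant heifer lay above the highest cyclic heifer. Over all transcripts tested, 2.36% separated the 5 and 5 heifers in either direction, where chance gives 0.794%. An unadjusted p under 0.05 was reached by 1074 transcripts, where chance gives 740.

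The transcripts that were higher included abundant ones. Their mean abundance in pregnant day 16 heifers had a median of 94.1 CPM, from 7.70 to 2240 CPM, and the 10 most abundant of the 141 held 38.5% of the counts of these 141 transcripts. ENSBTAT00000011146 rose from 9.20 ± 4.53 CPM (SD, n = 5) in cyclic to 578.5 ± 262 CPM (n = 5) in pregnant heifers, a log2 fold change of 5.99 (SE 0.92, edgeR adjusted p = 0.00122), and was higher in 5 of 5 pregnant heifers than in any cyclic heifer. ENSBTAT00000005991 was close to absent in cyclic day 16 heifers, with 1 count in all 5 together, and was present in every pregnant day 16 heifer at 8.94 to 27.2 CPM, with 212 counts in all. The ratio was 187 (95% exact counting interval 33.3 to 7440, counting error only), and the edgeR adjusted p was 2.01e-05.

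The 3 transcripts that were lower had log2 fold changes of -2.58, -2.47 and -0.69. ENSBTAT00000002431 fell from 11.4 ± 3.46 CPM (SD, n = 5) in cyclic to 1.64 ± 1.38 CPM (n = 5) in pregnant heifers, a log2 fold change of -2.47 (SE 0.44, edgeR adjusted p = 0.00182). The groups did not overlap with the libraries of heifer 12 summed. That heifer was the highest pregnant one at 3.72 CPM, against 6.27 CPM in the lowest cyclic heifer, and overlap was not examined with its library 1 alone. The log2 fold change was -3.18 without pregnant heifer 12. It was -3.12 with only library 2 of that heifer and -2.27 with only library 1. ENSBTAT00000026346, chosen after its values were seen, fell from 42.8 ± 27.0 CPM (SD, n = 5) to 7.09 ± 4.34 CPM (n = 5), a log2 fold change of -2.58 (SE 0.56, edgeR adjusted p = 0.0219). Its groups overlapped, since cyclic heifer 17 had 5.72 CPM, and it passed the threshold under 11 of 21 alternatives, with adjusted p from 0.000663 to 0.273.

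**Figure D2:**
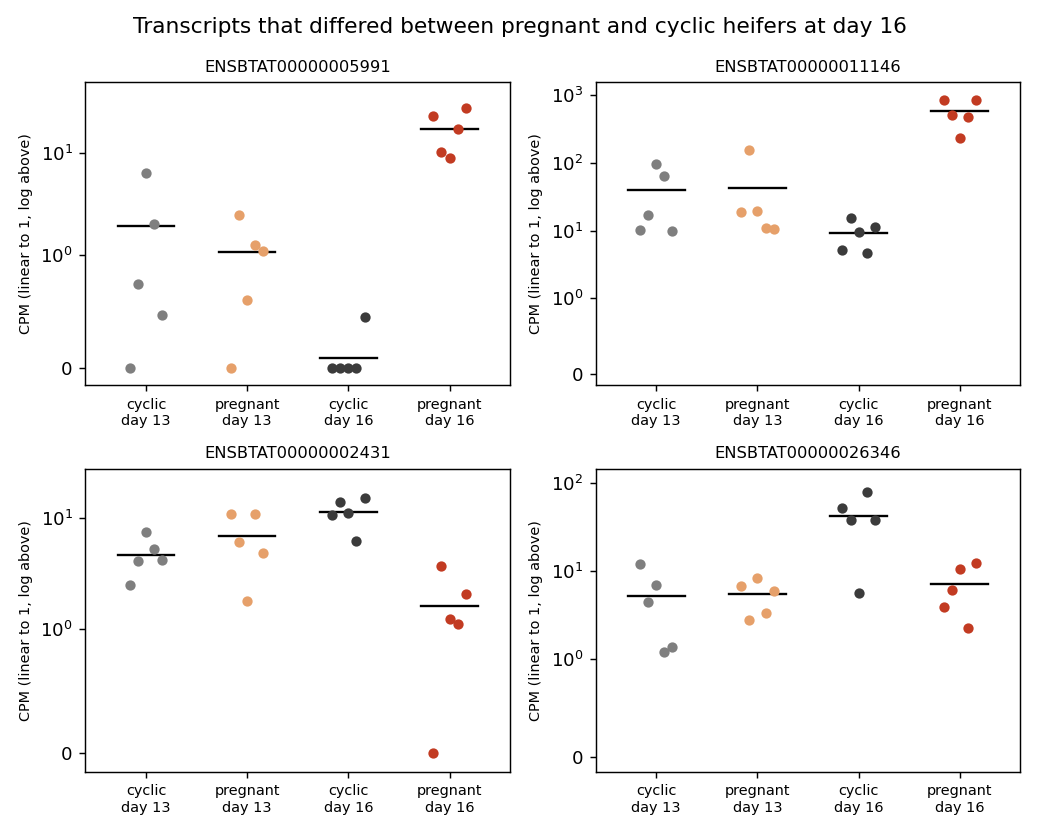
Points are single heifers and lines are group means, in CPM (scaled read counts) on an axis that is linear up to 1 and logarithmic above, with 5 heifers per group. The upper transcripts, ENSBTAT00000005991 and ENSBTAT00000011146, are higher in every pregnant day 16 heifer than in any other heifer, and the lower ones, ENSBTAT00000002431 and ENSBTAT00000026346, have a lower mean in pregnant than in cyclic heifers at day 16.

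As a group, the 141 transcripts took 0.640% ± 0.0623 (SD, n = 5) of the counts in cyclic day 16 heifers and 2.62% ± 0.614 (n = 5) in pregnant day 16 heifers. These heifers chose the set, so the difference is not independent evidence. When each heifer was left out and the set was chosen from the others, with 115 to 147 transcripts, the pregnant heifers left out lay 1.55 to 2.54 log2 units above the mean of the other cyclic heifers, and the cyclic heifers left out lay between -0.26 and 0.20 of it. Library 2 labelled heifer 12 matched heifer 19, so these 2 heifers were not fully held out. With that library moved to heifer 19, the pregnant heifers left out lay 1.51 to 2.56 above, with heifer 12 at 2.24 and heifer 19 at 1.51. Within run A the mean log2 CPM of the 141 was 2.40 higher in 2 pregnant than in 1 cyclic heifer, and within run C it was 2.03 higher in 2 pregnant than in 3 cyclic heifers. The same heifers chose the 141, so these differences within runs are not independent evidence either. Runs B and D held day 16 heifers of 1 group only.

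At day 13 no transcript passed the threshold between pregnant and cyclic heifers in edgeR, in either direction. The smallest adjusted p was 0.482, 1044 transcripts had an unadjusted p under 0.05 where chance gives 740, and 0.588% of the transcripts separated the 5 and 5 heifers where chance gives 0.794%. The number with an unadjusted p under 0.05 was 926 with the run letter in the model and 721 with limma voom. The excess over chance thus depended on the fit. DESeq2 called 0 transcripts and limma voom with quality weights called 1. In simulated data the edgeR test found 97% of 4-fold and 76% of 2-fold changes at day 13, so it would have missed part of the 2-fold changes. The simulation changed randomly drawn transcripts with the same dispersion in all groups, whereas pregnant day 13 heifers were the most variable. ENSBTAT00000005991 and ENSBTAT00000011146 had an SE of 0.78 and 0.77 at day 13, against a median of 0.19 over all transcripts. For transcripts as variable as these, 4-fold changes could also have been missed. The named transcripts did not pass the test at day 13, with edgeR adjusted p from 0.712 to 0.996. No transcript was called at both days.

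For the 141 transcripts that were higher in pregnancy at day 16, no difference between the day 13 groups was established, and a difference smaller than the spread between heifers could have been missed. They took 0.878% ± 0.252 (SD, n = 5) of the counts in cyclic and 0.907% ± 0.346 (n = 5) in pregnant day 13 heifers. The mean log2 CPM was 0.06 higher in the pregnant heifers, which was less than the spread between heifers (SD 0.40 in each group; exact two-sided permutation p = 0.865, smallest possible 0.00794). At day 13, 85 of the 141 were higher and 56 were lower in pregnant heifers, 8 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Pregnant heifer 14 had the highest level in its group, and without it the difference over the same 141 transcripts was -0.12. It was -0.07 and -0.01 without cyclic heifers 10 and 8, and 0.17 without cyclic heifer 18. Within runs the difference was 0.80 in run A (2 pregnant, 1 cyclic), -0.36 in run B (2 pregnant, 3 cyclic) and 0.16 in run C (1 and 1).

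**Figure D3:**
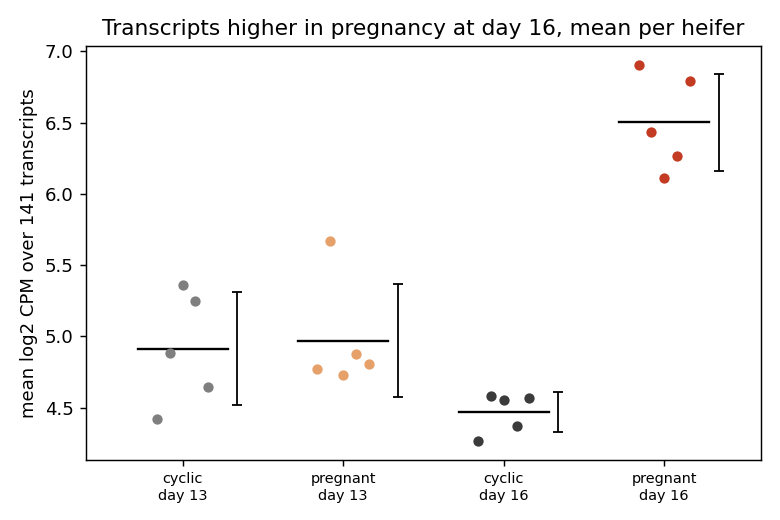
The vertical axis is the mean log2 CPM over the 141 transcripts called as higher in pregnancy at day 16. Points are single heifers, horizontal lines are group means and bars are 1 SD (n = 5 per group). The pregnant day 16 heifers sit between 6.11 and 6.91, the cyclic day 16 heifers between 4.27 and 4.58, and the day 13 groups overlap each other.

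The pregnancy effect at day 16 differed from that at day 13 for 65 transcripts by a direct test of the difference in edgeR. The signed difference, pregnant minus cyclic at day 16 less that at day 13, was positive in 63 and negative in 2. Of the 141 transcripts higher at day 16, 60 passed this test, but the difference contains the day 16 effect that chose them. The difference between the effects was 7.87 on the log2 scale for ENSBTAT00000005991 (edgeR adjusted p = 0.00204), a fitted value that rests on the single count in cyclic day 16 heifers. It was 5.87 for ENSBTAT00000011146 (edgeR adjusted p = 0.0306) and -3.04 for ENSBTAT00000002431 (edgeR adjusted p = 0.0138), and was not established for ENSBTAT00000026346 (-2.57, edgeR adjusted p = 0.329). DESeq2 called 124 transcripts.

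**Figure D4:**
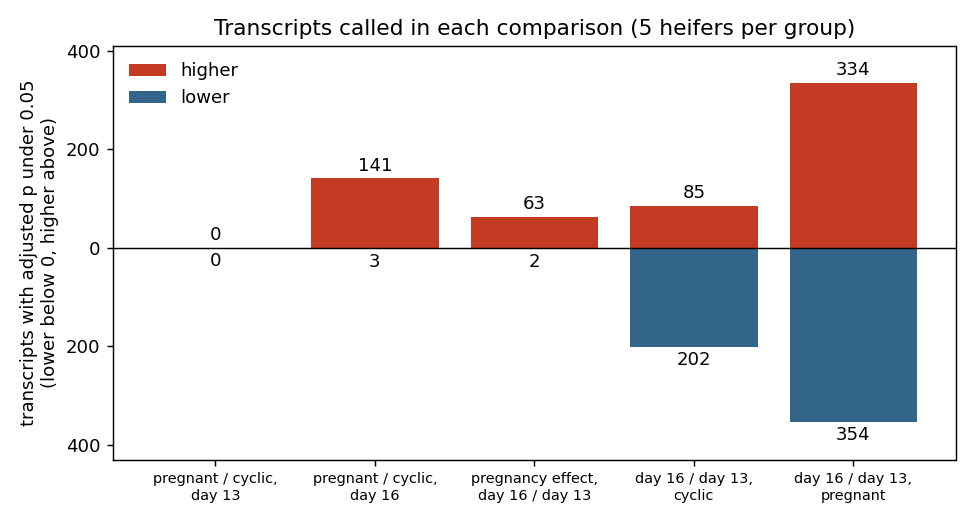
Bars give the number of the 14807 transcripts called in each of 5 comparisons at an adjusted p under 0.05, with those higher in the first-named group or day above 0 and those lower below 0. For the pregnancy effect, higher means a positive signed difference, day 16 less day 13. Pregnancy gave 0 calls at day 13 and 144 at day 16, and the change between days gave 287 calls in cyclic and 688 in pregnant heifers.

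Between day 13 and day 16, transcripts also changed without a conceptus. In cyclic heifers 85 transcripts rose and 202 fell (edgeR, n = 5 and 5), with median log2 fold changes of 1.05 and -1.12 and extremes of 4.43 and -4.52. In pregnant heifers 334 rose and 354 fell, with medians of 0.95 and -0.91 and extremes of 4.78 and -4.71. With the run letter in the model 150 transcripts were called in cyclic heifers, 142 of them among the 287, whose median change was 1.08 with and 1.09 without the run letter while their median SE rose from 0.22 to 0.26. It was 170 without cyclic day 16 heifer 3 and 453 without cyclic day 13 heifer 5, while DESeq2 called 475 and limma voom 509. The count in pregnant heifers was 451 without pregnant day 16 heifer 6, 587 with only library 1 of heifer 12 and 798 with only library 2. ENSBTAT00000026346 rose between the days in cyclic heifers (log2 fold change 2.98, SE 0.58, edgeR adjusted p = 0.00736) from 5.24 ± 4.52 CPM (SD, n = 5), and in pregnant heifers it had 5.45 ± 2.35 CPM (n = 5) at day 13 and did not pass (log2 fold change 0.41, SE 0.66, edgeR adjusted p = 0.790). ENSBTAT00000005991 and ENSBTAT00000011146 rose in pregnant heifers by 3.87 and 3.74 on the log2 scale (SE 0.61 and 0.79, edgeR adjusted p = 0.000380 and 0.00956), from 1.07 ± 0.900 and 43.0 ± 63.2 CPM at day 13. In cyclic heifers their means were 1.90 and 39.2 CPM at day 13 and 0.0895 and 9.20 CPM at day 16. These changes did not pass (log2 fold change -4.00 and -2.12, SE 1.21 and 0.90, edgeR adjusted p = 0.0958 and 0.260). The differences between their pregnancy effects thus hold lower cyclic values at day 16 as well as the rise in pregnant heifers. ENSBTAT00000002431 fell in pregnant heifers (log2 fold change -1.78, SE 0.46, edgeR adjusted p = 0.0236) and did not pass in cyclic heifers (log2 fold change 1.26, SE 0.40, edgeR adjusted p = 0.108).

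Many of these changes were shared by cyclic and pregnant heifers, 2 comparisons with no library in common. Both called 142 transcripts, 140 of them in the same direction. Of these, 29 rose in both where independent lists would share 1.92, and 111 fell in both where independent lists would share 4.83 (one-sided Fisher's exact test, p = 7.48e-27 and 1.78e-130, treating transcripts as independent, which they are not). Of the 287 transcripts called in cyclic heifers, 93.0% had the same direction in pregnant heifers, where their median change in that direction was 0.70 against 1.09 in cyclic heifers. Within runs this median in pregnant heifers was 0.64 in run A (2 heifers at each day), 0.91 in run B (1 at day 16, 2 at day 13) and 0.59 in run C (2 at day 16, 1 at day 13). Of the 688 called in pregnant heifers, 75.4% had the same direction in cyclic heifers, with a median of 0.32 against 0.94. Each list was chosen by the change in its own group, which raises the median there. The smaller medians in the other group thus do not by themselves show a weaker change. The direct test of the difference was passed by 5 of the 287 and by 62 of the 688. That difference contains the day changes that chose both lists, so these counts are not independent of the choice. In simulated data this test found 37% of 2-fold changes.

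**Figure D5:**
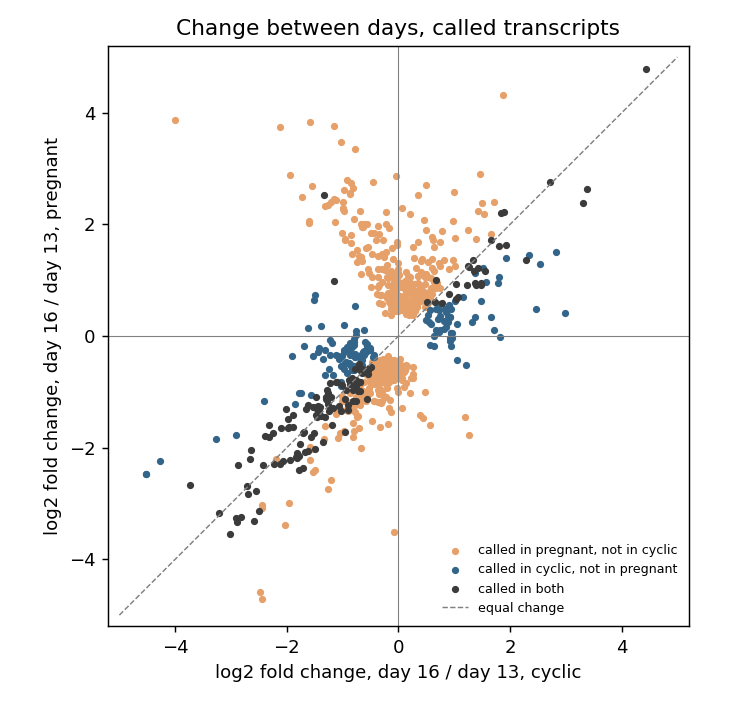
Each point is a transcript called between day 13 and day 16 in cyclic heifers, in pregnant heifers or in both, placed by its log2 fold change in cyclic (horizontal) and pregnant heifers (vertical), and the dashed line marks equal change. Of the 142 called in both (dark), 140 lie in the quadrants where both changes have the same sign.

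Across all 14807 transcripts, edgeR fold changes between days in cyclic and pregnant heifers had a Pearson correlation of 0.320 (Spearman 0.169). The reassignments used differences of mean log2 CPM, for which the Pearson correlation was 0.31. That value lay within the range of -0.354 to 0.376 that held 95% of 1000 reassignments of the heifers (permutation p = 0.0929). The edgeR fold changes for pregnancy at day 13 and day 16 had a Pearson correlation of -0.108 (Spearman -0.257). From mean log2 CPM it was -0.119, within -0.293 to 0.278 (permutation p = 0.438). Neither of these 2 Pearson correlations from mean log2 CPM lay outside the range that held 95% of the reassignments. The Spearman correlations were not set against reassignments.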

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

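The tests of library identity and of scaling, and the sum of library 2 with heifer 19, were chosen after the results they bear on had been seen.

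Heifers that stood far from the rest of their group were sought in 24 sets of 5 values, and 3 values were found, where chance gives about 1 in 20 sets. They are not 3 separate findings, since 2 come from the same heifer and related transcripts and the third is a single count among values of 0, which any such count would give. Pregnant day 13 heifer 14 had a mean of 5.67 log2 CPM over the 141 transcripts higher in pregnancy at day 16, against 4.73 to 4.88 in the other 4. The same heifer had 156 CPM of ENSBTAT00000011146, against 10.5 to 19.1 CPM in the others. Cyclic day 16 heifer 7 had 0.448 CPM of ENSBTAT00000005991, a single count, against 0 in the others.

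The effect of pregnancy differed between days for 65 transcripts by the direct edgeR test. Among the named transcripts the effect at day 16 exceeded that at day 13 by 7.87 for ENSBTAT00000005991 and 5.87 for ENSBTAT00000011146 on the log2 scale, and the difference was -3.04 for ENSBTAT00000002431.

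The 2 libraries labelled heifer 12 ranked 51 of 210 pairs in closeness, which argues against their holding RNA of 1 heifer and differing only by lane. Both carried run letter A, so by that reading of the letters they did not differ by run. The library labelled heifer 19 carried run letter B. Library 2 and the library labelled heifer 19 correlated at 0.965 over the on-off transcripts, above the 0.690 that was the highest such correlation among the remaining pairs, so they may hold RNA of the same heifer. Which of the labels is right stays open, and no biological explanation was tested. Pregnancy at day 16 gave 142 calls with library 1 alone and 144 with library 2 moved to heifer 19. The day effect in pregnant heifers gave 587 calls with library 1 alone and 798 with library 2 alone, against 688 with the sum.

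Most transcripts called for pregnancy at day 16 were higher. The scaling of the libraries is argued against as the cause of the higher level of these transcripts, since a scaling factor shifts all transcripts of a heifer alike. Taken against the median of its own transcripts, the set chosen without a heifer lay at least 1.51 log2 units higher in each pregnant heifer left out than in the cyclic heifers, and at most 0.24 higher in a cyclic heifer left out, with library 2 moved to heifer 19. This follows only transcripts chosen as higher, so it does not address why few were lower. Under other size factors and DESeq2 at least 95.7% of the calls were higher. Unequal depth is argued against as the cause of the imbalance, since 97.7% of the calls were higher after every heifer was thinned to 1256870 counts. An effect of the conceptus, as named by the design, is a candidate explanation, and a changed makeup of cell types in the tissue was not tested. Pregnant heifers were inseminated and kept only with a conceptus at the proper stage, and cyclic heifers were not inseminated. The design cannot tell the conceptus apart from insemination or from this selection.

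The change between days in cyclic heifers lay partly along the sequencing runs, since run B held 3 day 13 and 0 day 16 cyclic heifers. With the run letter in the model, the 287 transcripts called in cyclic heifers had a median change of 0.74 (log2) in the same direction in pregnant heifers, whose runs were nearly balanced, with 93.4% in that direction and quartiles of 0.34 and 1.33. This argues against the runs as the whole cause. In cyclic heifers the run term left 142 of the 287 called. Over all 287 the median change was 1.08 with it and 1.09 without, and the median SE rose from 0.22 to 0.26. These medians do not separate the transcripts that lost their call from those that kept it. For single transcripts the share of the run stays open.

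Other divisions of the heifers were fitted in the same way, 100 per comparison with the real one included. For pregnancy at day 16 only 1 of 100, the real one, gave as many calls (144, highest other 3). For the day effect in pregnant heifers it was likewise 1 of 100 (688, highest other 19). The difference between the pregnancy effects gave 65 calls against at most 40 in other divisions, with 1 of 100 as large. In these comparisons library 2 labelled heifer 12 was summed into heifer 12, although it matched heifer 19. These heifers may thus share RNA, and the real division keeps them in the same group while others can part them. The divisions were not fitted again with that library moved or left out. The real division thus gave the most calls of those drawn, but chance cannot be excluded at a stated level. For the day effect in cyclic heifers 1 of 100 was as large (287, highest other 121), and the highest other division was the real one with cyclic heifers 5 and 15 exchanged, which were sequenced in runs B and A. For pregnancy at day 13 the real division gave 0 calls and so all 100 gave as many. One other division gave 52, setting cyclic heifers 8, 10 and 13 and pregnant heifers 2 and 11 against the rest, and it may reflect a structure among the day 13 heifers. It is the highest of those drawn, and whether unstructured heifers would give as many was not tested. On the first principal component of log2 CPM, heifers 2, 8, 10, 11 and 13 lay between -42.9 and -20.3. The other day 13 heifers lay between -18.9 and 30.5, so this division followed that component.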

How the results depend on the processing

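Thinning to the smallest total, library 2 moved to heifer 19, and the day 13 set and shared day calls under each setting were tests chosen after the data were seen. Calls for pregnancy at day 16 numbered 123 to 197 under the alternatives and 118 to 150 with a heifer left out (main value 144), sharing at least 116 with it, and at least 92.4% were higher. Pregnancy at day 13 gave 0 calls in all alternatives except limma voom, with 1. The difference between the pregnancy effects gave 124 calls with DESeq2, all 65 included, and 54 to 91 with a heifer left out (91 without pregnant day 13 heifer 14). The day effect in cyclic heifers gave 475 calls with DESeq2, 509 with voom and 150 with the run term, and 170 (without cyclic day 16 heifer 3) to 453 (without cyclic day 13 heifer 5) with a heifer left out. In pregnant heifers it gave 546 to 930, and 451 (without pregnant day 16 heifer 6) to 660 with a heifer left out. The cause of these shifts was not tested, though the run term raised the median SE of the transcripts called in cyclic heifers. The day correlation was 0.146 without the filter and 0.195 with DESeq2, 2 fits that admit transcripts of few counts, and 0.259 to 0.383 with a heifer left out. The pregnancy correlation stayed negative, from -0.180 to -0.0387 in all but the fit without pregnant day 13 heifer 9 (-3e-04). Transcripts changed in the same direction in both day comparisons numbered 102 to 218, against 140. The day 13 difference of the day 16 set, chosen again in each fit, ran from -0.14 to 0.15 with a heifer left out, never past the threshold, and with the 141 kept from -0.12 to 0.17. ENSBTAT00000026346 kept its direction in 21 of 21 alternatives and its call in 11, while the other 3 named transcripts kept both. Alternatives that need gene names (the gene list tests with camera and fry, the interferon-stimulated list means and the epithelial minus stromal covariate) were not run. Depth limits transcripts near 3 counts, which is 0.532 to 2.38 CPM per heifer.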

Other observations

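The test of whether the day 16 transcripts move together at day 13 was chosen after those transcripts were known and before its result was seen. Its repeats per group and without single heifers were chosen after.

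The 141 transcripts that were higher in pregnancy at day 16 varied together among heifers at day 13. The SD of their mean between day 13 heifers, within groups, was 0.40 log2 units, against a median of 0.03 and a highest value of 0.09 in 10000 random sets of 141 transcripts matched on mean abundance, so the set lay at percentile 100, where the threshold set beforehand was 95. In the 5 cyclic heifers the SD was 0.40, and 0.33 to 0.46 with any of them left out, above all random sets. In the 5 pregnant heifers the SD was also 0.40 and came mostly from heifer 14, without which it was 0.06, still above that threshold (percentile 98.5) but below the highest random set (0.13). Pregnant heifer 14 was 0.70 above its group mean with 117 of the 141 above, cyclic heifer 18 was 0.45 above with 118 above, cyclic heifer 5 was 0.34 above with 107 above, and cyclic heifer 10 was 0.49 below with 9 above. ENSBTAT00000011146 stood at 156, 96.2 and 62.9 CPM in heifers 14, 18 and 5, and at 9.78 to 19.1 CPM in the other 7 at day 13. The hypothesis tested, that the set may move as a unit among day 13 heifers, met that threshold in both groups, with and without any single heifer, by a small margin in pregnant heifers without heifer 14. Why it varies was not tested. The random sets were not matched on variability, and their members were not chosen for differing together as the 141 were at day 16. A set of transcripts regulated together would be likely to pass, so the test shows shared variation and nothing of its source. A difference in the makeup of the tissue stays open, since cell type markers could not be named.

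The first and second principal components of log2 CPM held 18.5% and 17.5% of the variance. On the second, pregnant day 16 heifers lay between -44.8 and -11.7, pregnant day 13 heifers between 6.50 and 38.1, cyclic day 16 heifers between -17.4 and 18.1 and cyclic day 13 heifers between -7.35 and 22.97, so the cyclic day 16 range overlapped those of the other 3 groups. The median variance of log2 CPM between heifers was 0.107 in pregnant day 13, 0.0799 in cyclic day 13, 0.0694 in cyclic day 16 and 0.0683 in pregnant day 16 heifers, with 5 heifers in each.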
